A study of Mus musculus with 15 samples.

How the data were processed

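RNA from sorted fluorescent nuclei of individual mouse cortices was amplified with a SMART-Seq ultralow input kit, made into libraries with Nextera XT and sequenced as single-end reads on a NextSeq500, per the labels' protocols. The authors deposited 1 table of raw counts per gene for each of the 15 libraries. Reads were aligned with Bowtie2 2.5.3 and counted with HTSeq, against mm10 (GRCm38), per the submitters' processing notes. The annotation release, the counting mode, the treatment of reads with several alignments and the strand setting are not given in the sources used here, so counts of overlapping genes, antisense genes and near-identical copies are uncertain. The amplification and library kits do not mark strand. Amplified reads carry no molecular identifiers, so a floor of 3 counts covers counting error only.

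The deposited counts came in 2 sets with different gene lists. The PTU and PTU_TH tables hold 55341 genes and those of Ctrl and Mut hold 48321. Of these, 46380 share a symbol, and a further 579 renamed genes were matched through older symbols. The renamed genes were included where results of Mut against Ctrl were set beside those of PTU_TH against PTU. Comparisons of PTU or PTU_TH with Ctrl, and of the PTU and Mut effects, used only genes with a shared symbol. Renamed genes and genes without a counterpart were left out there. Positions, gene types and exon overlaps were taken from GENCODE M21 for GRCm38, which names 55327 of the symbols of the former set and 46394 of those of the latter; symbols that name more than 1 gene were left without a position. Every table column belonged to a library of this series.

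Groups and replicate numbers were taken from the sample titles and the series design. The titles number separate mice, so replicates were read as animals. Comparisons were PTU_TH against PTU and Mut against Ctrl, each within 1 set, and PTU against Ctrl and PTU_TH against Ctrl, across the sets. Each used only its own libraries and edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter with a minimum count of 10, robust quasi-likelihood fits and Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 were called. The common biological coefficient of variation was 23.0% for PTU_TH against PTU, 27.8% for Mut against Ctrl, 23.3% for PTU against Ctrl and 21.9% for PTU_TH against Ctrl. Depths of 12957838 to 32571175 counts per library gave, in simulated data with 200 changed genes, recovery of 74% of 2-fold and 97% of 4-fold changes for PTU_TH against PTU. Recovery was 73% and 100% for Mut against Ctrl, 73% and 100% for PTU against Ctrl, and 83% and 100% for PTU_TH against Ctrl. In the same order of comparisons, 16 of 187, 11 of 184, 10 of 183 and 14 of 197 calls were false. The changed genes were drawn only from those with a mean of at least 5 CPM. Simulated genes varied independently, without the structure between libraries described below. Recovery of lower genes, or under that structure, was not measured.

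The comparisons, the tests, 25 gene lists and the rule for named genes were fixed before the data were examined. The lists cover hormone-induced, hormone-repressed and hormone signalling genes, parvalbumin neuron genes, ion channels, transmitter receptors, perineuronal nets, vesicle release, neuropeptides, circadian and immediate early genes, mitochondria, cholesterol synthesis, heat shock and markers of other cell types. Lists with at least 5 measured members, 22 per comparison, were tested with limma 3.58.1 by camera at a preset correlation of 0.01, again with an estimated correlation, and by fry, each adjusted over the lists of a comparison. The genes named are, per comparison, up to 8 with the largest rise and 8 with the largest fall among called genes of at least 5 CPM whose groups do not overlap and whose symbol is not a predicted model. Added to these are up to 4 called members of each list, or the 2 members with the smallest p where none was called, and Thra, Thrb, Pvalb, Klf9 and Hr; other genes are named as members of a count. Some genes that meet this rule are not reported here. A fold against a group at 0 in every library is given as a bound.

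Hormone-responsive genes called in PTU_TH against PTU were tested as sets in Mut against Ctrl with camera and fry, and the overlap of calls with Fisher's exact test. For PTU and Mut, which share the Ctrl libraries, unchanged groups were simulated against those controls. Alternatives were DESeq2 1.42.0, RLE and upper quartile scaling, other filters, 1 fit of all groups, limma-voom with quality weights, a surrogate variable from sva 3.50.0, a marker covariate, a 2-fold threshold, a replicate block, and omission of each library. Sex as a covariate, read from the Y-linked genes with a threshold of 50 CPM, and the exclusion of genes with shared exons were added after seeing the data. Xist had 0 counts in every library, and its antisense gene Tsix had 0.859 to 1.64 CPM in the libraries without Y-linked counts and at most 0.0399 CPM in the others, so sex was read from Y-linked genes. Genes of sex chromosomes used for this purpose are not reported as results.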

Results

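Nuclear RNA was sequenced from parvalbumin neurons, the fast-spiking inhibitory interneurons of the cerebral cortex, sorted as fluorescent nuclei from adult mice in which Cre is driven by the parvalbumin gene. The 15 libraries came from 4 groups of mice. Ctrl (n = 4) were untreated animals with wild-type Thra, the gene of thyroid hormone receptor alpha. Mut (n = 4) were littermates carrying a floxed Thra allele that expresses a dominant negative receptor. PTU (n = 3) received propylthiouracil, a blocker of thyroid hormone synthesis, in food for 2 weeks, and PTU_TH (n = 4) received the same diet plus an intraperitoneal injection of thyroid hormone 24 h before dissection. Ctrl and Mut libraries held 22333742 to 32571175 counts over 21337 to 22577 genes. PTU and PTU_TH libraries held 12957838 to 19141683 counts over 19618 to 20586 genes. Libraries of 1 group differed by more than counting noise in every pair (chi-square per degree of freedom from 7.20 to 105), a noise that leaves out amplification. Their Spearman correlations were 0.955 to 0.989. Each was counted as a separate sample because the titles number separate mice. Values are CPM, counts scaled to a common library total, as mean ± SD over libraries, and positions are those of the GRCm38 annotation.

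The libraries also differed within groups in a way the labels do not describe. Genes of the Y chromosome had counts in Ctrl replicate 2, in Mut replicates 1, 2 and 3, in PTU replicates 6 and 7 and in PTU_TH replicates 3 and 4. The other libraries had almost none. In the PTU and PTU_TH libraries, genes longer than 100 kb took 24.9% to 28.4% of the counts where Y-linked counts were present and 34.1% to 40.7% where they were absent. In Ctrl and Mut the corresponding ranges were 27.4% to 36.7% and 31.6% to 39.7%. The largest component of the differences within PTU and PTU_TH held 56.6% of that variance. Its gene loadings followed gene length (Spearman −0.59 across 15247 genes, which are not independent replicates). In Ctrl and Mut the first component held 38.7%, and its gene loadings followed gene length too (Spearman −0.45 across 16701 genes, likewise not independent replicates). Mut replicate 2 stood apart on this component and had the lowest share of long genes in its set (27.4%).

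**Figure D1:**
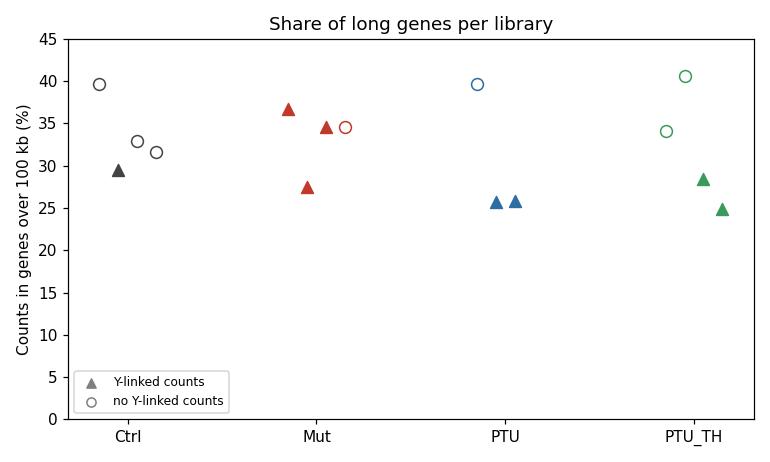
Share of counts in genes longer than 100 kb (percent, vertical axis) for each library, by group; filled triangles are libraries with Y-linked counts and open circles those without. In PTU and PTU_TH the libraries with Y-linked counts lie between 24.9% and 28.4% and the others between 34.1% and 40.7%.

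The injection of thyroid hormone into PTU mice asked which genes of parvalbumin neurons respond to the hormone within 24 h. Hr, which encodes a corepressor and is a known direct target of thyroid hormone receptors in brain, rose from 3.82 ± 1.60 CPM in PTU (n = 3) to 46.6 ± 3.41 CPM in PTU_TH (n = 4), a 12.2-fold difference. Cacnb3, an auxiliary subunit of voltage-gated calcium channels, rose from 29.3 ± 4.60 to 98.4 ± 6.41 CPM. Sema7a, a membrane-anchored semaphorin, rose from 34.4 ± 2.74 to 82.4 ± 8.96 CPM. Acan, which encodes aggrecan, the main proteoglycan of perineuronal nets, rose from 48.4 ± 4.92 to 85.6 ± 8.91 CPM. Fewer genes fell. Srpk3, an X-linked protein kinase gene, fell from 89.8 ± 6.59 to 37.7 ± 7.62 CPM. Camk1, a calcium/calmodulin-dependent kinase gene, fell from 174 ± 11.8 to 105 ± 4.22 CPM.

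By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold change was 3.61 ± 0.25 (SE) for Hr (chromosome 14, 70552212 to 70573548; adjusted p = 0.00251) and 1.75 ± 0.13 for Cacnb3 (chromosome 15, 98630840 to 98644529; adjusted p = 0.00251). By the same edgeR test it was 1.26 ± 0.12 for Sema7a (adjusted p = 0.00689) and 0.82 ± 0.12 for Acan (chromosome 7, 79053483 to 79115099; adjusted p = 0.0422). The other genes with the largest rises were Dab2, an endocytic adaptor (2.09), Ung, a uracil-DNA glycosylase (1.93), Slc35g1 (1.87), Mrvi1 (1.86), Flywch2 (1.75) and the pseudokinase gene Trib1 (1.59). Their edgeR adjusted p ranged from 0.0118 for Flywch2 to 0.0451 for Mrvi1. Besides Srpk3 (−1.25) and Camk1 (−0.72), Plxna3, a semaphorin receptor gene (−0.95), and Izumo4 (−0.79) fell. Their edgeR adjusted p ranged from 0.0202 for Srpk3 to 0.0477 for Izumo4. In all, 43 of 15288 genes changed, 39 upward and 4 downward. At an unadjusted p under 0.05 there were 1126, the 43 included. The ranges of the groups did not overlap for any of the 43, against 8.59% of all genes and 5.71% by chance. Omitting 1 library gave 27 calls (without PTU replicate 5), 10 (without PTU replicate 6) or 12 (without PTU replicate 7). It gave 5 (without PTU_TH replicate 1), 18 (without PTU_TH replicate 2), 11 (without PTU_TH replicate 3) or 29 (without PTU_TH replicate 4). In the same order, 26, 10, 12, 5, 18, 11 and 27 of these calls were among the 43. Hr and Cacnb3 passed each time. Sema7a passed in 6 of the 7, and Flywch2 and Ung in 4 (edgeR adjusted p = 0.0728 and 0.0880 without PTU_TH replicate 1). Srpk3 passed in 3 of the 7, Plxna3, Dab2 and Mrvi1 in 2, and Camk1 and Izumo4 in 1, with edgeR adjusted p up to 0.193 for Camk1 and 0.274 for Izumo4 without PTU replicate 6. No lowered gene was left without PTU replicate 6, PTU replicate 7 or PTU_TH replicate 1. Acan, Slc35g1 and Trib1 passed in none, and the edgeR adjusted p for Acan reached 0.243 without PTU replicate 6. Several other models called more genes, and a larger share of them lower. DESeq2 called 158 higher and 45 lower, limma-voom 128 and 43, and glial and excitatory markers as a covariate 122 and 33. Sex as a covariate (chosen after seeing the data) called 241 and 94, and a surrogate variable 649 and 410. All 43 were among the genes called by each of these. A fit to all 4 groups called 42 genes and kept 26 of the 43, and upper quartile and RLE scaling called 40 each and kept 38 and 40.

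Among the fixed gene lists, the known thyroid hormone-induced genes moved most clearly upward: 15 of 17 measured members had a positive change, with a median of 0.56. Hr, Dbp (a circadian transcription factor, 1.19), Flywch2, Sema7a and Abcd2 (a peroxisomal fatty acid transporter, 0.62) rose over all genes tested. Dbp passed in 4 of 7 omissions of 1 library (edgeR adjusted p = 0.0776 without PTU replicate 7). When adjusted over the list alone 9 members passed, adding Klf9 (0.99, adjusted p = 0.0556 over all genes), Shh, Gls2 and Itga7. The list passed limma's camera test (adjusted p = 1.81e-14; adjusted p = 0.0743 with an estimated correlation) and the fry test (adjusted p = 0.00468). Perineuronal net genes had a median of 0.14, with Acan called of 23, also 1 when adjusted over the list alone. They passed camera (adjusted p = 0.0261; adjusted p = 0.317 with an estimated correlation; 0.157 without PTU replicate 5). Of 50 potassium channel genes none was called over all genes and 1, Kcng4, a modifier subunit of Kv2 channels (1.24), when adjusted over the list alone. The list passed camera upward (adjusted p = 0.0207; adjusted p = 0.562 with an estimated correlation; 0.140 without PTU_TH replicate 2). Of 29 sodium, calcium and HCN channel genes Cacnb3 was called, also 1 when adjusted over the list alone. This list passed camera upward too (adjusted p = 0.0457; adjusted p = 0.679 with an estimated correlation; 0.498 without PTU_TH replicate 2). The levels of both lists also went with the presence of Y-linked counts. The potassium channel genes summed to 12842 to 16046 CPM in the 3 libraries without Y-linked counts and 8929 to 10426 in the 4 with them. The other channel list summed to 7559 to 10405 and 5279 to 6208 CPM.

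Downward, neuropeptide genes passed camera (12 of 15 negative, median −0.43, adjusted p = 0.0207; adjusted p = 0.679 with an estimated correlation; 0.0937 without PTU replicate 6). No member was called over all genes or adjusted over the list alone. The members with the smallest p were Cort (−0.82) and Crhbp (−0.85). Immediate early genes of neuronal activity passed downward (15 of 21 negative, median −0.18, adjusted p = 0.0457; adjusted p = 0.679 with an estimated correlation; 0.299 without PTU_TH replicate 3). So did known hormone-repressed genes (8 of 11 negative, median −0.42, adjusted p = 0.0457; adjusted p = 0.679 with an estimated correlation; 0.200 without PTU_TH replicate 2). Each of these lists held 0 called members, also 0 when adjusted over the list alone. Markers of excitatory neurons, a cell type the sort should exclude, moved in the same direction (13 of 15 negative, median −0.29, adjusted p = 0.0207; adjusted p = 0.653 with an estimated correlation; 0.0957 without PTU replicate 6). Markers of astrocytes did so too (10 of 13 negative, median −0.28, adjusted p = 0.0457; adjusted p = 0.679 with an estimated correlation; 0.290 without PTU_TH replicate 1). The mean log2 CPM of neuropeptide genes also went with Y-linked counts. It was 2.22 to 2.69 in the 3 libraries without them and 2.82 to 3.28 in the 4 with them. Excitatory markers had 2.21 to 2.49 and 2.56 to 2.98, and astrocyte markers 1.89 to 2.43 and 2.57 to 2.76. For immediate early and hormone-repressed genes these ranges overlapped. Summed CPM reversed the direction for astrocyte markers. Their sums were 459 to 535 CPM in the 3 libraries without Y-linked counts and 378 to 417 in the 4 with them. For excitatory markers and neuropeptide genes the ranges of summed CPM overlapped. How the markers of other cell types went with Y-linked counts thus depended on the measure. Summed over the 15 excitatory markers measured, the level was 458 ± 64.3 CPM in PTU and 441 ± 59.6 in PTU_TH. The corresponding sums over 27 parvalbumin neuron genes were 12560 ± 2673 and 12979 ± 2332 CPM. Camera with an estimated correlation called 0 of the 22 lists. Fry called 2, the hormone-induced list and the perineuronal net list (adjusted p = 0.0255 for the latter). The hormone-induced list passed camera in all 7 omissions of 1 library, and no other list did.

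The comparison of Mut with Ctrl littermates asked what a dominant negative receptor alters in these neurons. Thra itself, the gene that carries the altered allele (chromosome 11, 98740638 to 98769006), measured 60.7, 56.7, 48.3 and 62.2 CPM in the 4 Ctrl libraries and 29.6, 27.8, 37.9 and 32.1 CPM in the 4 Mut libraries. Thra is among the genes with shared exons, whose counts are uncertain. Itga7, an integrin subunit gene, fell from 77.0 ± 8.67 to 21.7 ± 1.28 CPM. The collagen genes Col24a1 (75.4 ± 10.6 to 19.9 ± 2.74 CPM) and Col16a1 (107 ± 16.7 to 25.1 ± 7.22 CPM) fell with it. Scn4b, a sodium channel beta subunit, fell from 105 ± 10.9 to 44.9 ± 1.80 CPM and Kcng4 from 61.8 ± 12 to 18.1 ± 6.44 CPM. Acan fell from 63.2 ± 6.25 to 31.9 ± 1.07 CPM and Hr from 14.2 ± 1.66 to 1.72 ± 1.5 CPM. In the other direction, Tac1, the substance P precursor, rose from 104 ± 13.2 to 234 ± 70.5 CPM and Rbp4, a retinol carrier, from 17.0 ± 2.22 to 52.5 ± 15.2 CPM. Rbp4 is on the fixed list of markers of excitatory neurons, a cell type the sort should exclude. It was the only called member of the 15 measured, and that list did not pass camera (adjusted p = 0.438).

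The log2 fold changes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were −1.82 ± 0.13 (SE) for Itga7 (adjusted p = 0.000162), −1.92 ± 0.15 for Col24a1 (adjusted p = 0.000359) and −1.23 ± 0.11 for Scn4b (adjusted p = 0.00116). By the same edgeR test they were −0.99 ± 0.12 for Acan (adjusted p = 0.00708), −3.06 ± 0.50 for Hr (adjusted p = 0.0259) and −0.84 ± 0.14 for Thra (adjusted p = 0.0280). Col16a1 (−2.09), Tesc, a calcium-binding protein gene (−1.87), Kcng4 (−1.77), Cacnb3 (−1.64) and Sema7a (−1.28) fell with edgeR adjusted p from 0.00124 to 0.0259. Arhgap22, of whose exonic bases 36.9% are shared with another gene, fell by 3.49 on the log2 scale. Higher in Mut were Treh, the trehalase gene (2.22), Zcchc12 (1.76), Rbp4 (1.62), Fam150b, a ligand of the kinases Alk and Ltk (1.52, with 35.1% of its exonic bases shared), Ppfibp1 (1.37), Armc2 (1.25), the amino acid transporter gene Slc7a3 (1.22) and Tac1 (1.17). Their edgeR adjusted p ranged from 0.00708 for Rbp4 to 0.0380 for Ppfibp1. In all, 59 of 16949 genes changed, 21 upward and 38 downward, and 1481 had an unadjusted p under 0.05. No group ranges overlapped for the 59, against 6.12% without overlap among all genes and 2.86% by chance. Omitting 1 library gave 43 calls (without Ctrl replicate 1), 19 (without Ctrl replicate 2), 11 (without Ctrl replicate 3) or 13 (without Ctrl replicate 4). It gave 11 (without Mut replicate 1), 103 (without Mut replicate 2), 36 (without Mut replicate 3) or 16 (without Mut replicate 4). In the same order, 33, 18, 11, 13, 11, 58, 34 and 15 of these calls were among the 59. Acan, Arhgap22, Col16a1, Col24a1, Fam150b, Itga7 and Scn4b passed in all 8 omissions. Cacnb3 and Rbp4 passed in 7, Zcchc12 in 6, Slc7a3 in 4, and Tesc, Armc2 and Kcng4 in 3 (for Kcng4, edgeR adjusted p = 0.0703 without Ctrl replicate 4). Hr, Sema7a, Thra and Treh passed in 2 and Tac1 and Ppfibp1 in 1, with edgeR adjusted p up to 0.111 for Hr (without Mut replicate 1) and 0.137 for Thra (without Ctrl replicate 4). Y-linked counts were present in 3 of 4 Mut and 1 of 4 Ctrl libraries. With sex as a covariate, chosen after seeing the data, 31 genes passed, 27 of them among the 59 and Thra not (−0.83, edgeR adjusted p = 0.120). DESeq2 called 399, limma-voom 331, a fit to all 4 groups 196, a surrogate variable 177 and a floor of 1 CPM 90.

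Known hormone-induced genes had lower levels in Mut as a list, with 15 of 18 members negative and a median of −0.50. Hr, Sema7a and Itga7 fell over all genes, and 4 members, adding Nefh (a neurofilament subunit, −0.85), when adjusted over the list alone. The list passed camera (adjusted p = 8.67e-08; adjusted p = 0.282 with an estimated correlation) and fry (adjusted p = 0.0476). Neuropeptide genes passed camera upward (12 of 15 positive, median 0.59, adjusted p = 0.00129; adjusted p = 0.50 with an estimated correlation; 0.0775 without Mut replicate 2). Tac1 was called over all genes, and 6 when adjusted over the list alone, namely Tac1, Npy (0.72), Cck (0.84), Cort (0.89), Nppc (0.89) and Crhbp (0.61). Npy and Cck are also the 2 of 11 markers of other interneurons that passed over that list alone. The markers summed to 197 ± 9.56 CPM in Ctrl and 267 ± 45.3 in Mut and did not pass camera (adjusted p = 0.227). Immediate early genes also passed upward (19 of 23 positive, median 0.52, adjusted p = 0.00170; adjusted p = 0.50 with an estimated correlation). Of these, 0 were called over all genes and 2, Vgf (0.98) and Nr4a2 (1.63), when adjusted over the list alone. Among 52 potassium channel genes 2 fell, Kcng4 being 1 of them, and 4 when adjusted over the list alone. Among 30 sodium, calcium and HCN channel genes Scn4b and Cacnb3 fell, with 3 lower and 1 higher when adjusted over the list alone. Neither list passed camera (adjusted p = 0.227 for both). Of 24 perineuronal net genes Acan fell, with 4 lower and 1 higher when adjusted over the list alone, and the list had a camera adjusted p of 0.671. Camera with an estimated correlation called 0 of 22 lists and fry called 1.

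**Figure D2:**
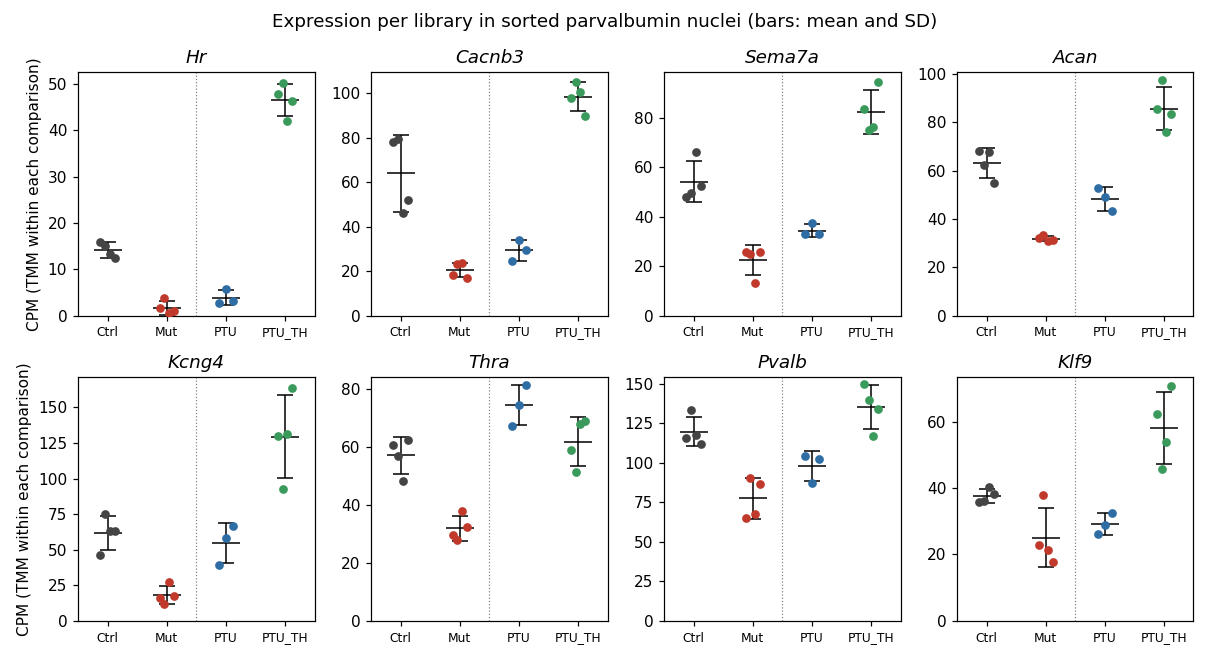
CPM (vertical axes, starting at 0) of 8 genes in each library, by group, normalised within Ctrl and Mut and within PTU and PTU_TH, which the dotted line separates; points are libraries and bars the mean and SD. Hr lies between 42.1 and 50.2 CPM in PTU_TH and at 5.66 CPM or below in PTU, and Thra is lower in each Mut library than in any Ctrl library.

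Genes that responded to the hormone moved the opposite way in the mutant. Of the 39 genes raised by the injection, 37 were lower and 2 higher in Mut than in Ctrl, with a median log2 fold change of −0.99. All 4 genes lowered by it, Srpk3, Camk1, Plxna3 and Izumo4, were higher in Mut (median 0.67), and none of these 4 was called there. The raised genes called lower in Mut were 14: Hr, Cacnb3, Sema7a, Acan, Tesc, the orphan receptor gene Gpr83, the extracellular matrix gene Npnt, Vash2, Rgcc, Frmpd1, Faap100, Kmt5c and the predicted genes 4632428C04Rik and Gm10684. Those from Gpr83 on were outside the rule for named genes and are listed because they make up this overlap. The expected overlap of independent lists was 0.103 of 14366 genes (two-sided Fisher's exact test, p = 7.72e-28). Fisher's test treats genes as independent, which they are not, so its p does not measure the spread between mice. No gene was called in the same direction in both comparisons, which share no library. As sets in Mut, the raised genes passed limma's camera (p = 2.24e-37; p = 5.44e-06 with an estimated correlation) and fry (p = 1.55e-07). So did the lowered genes (camera p = 8.96e-06; p = 0.0243 with an estimated correlation; fry p = 0.00383). Read the other way, of the genes called in Mut, 20 of 20 raised ones were lower in PTU_TH than in PTU (median −0.62, camera p = 4.42e-16; p = 0.000710 with an estimated correlation). Of the lowered ones, 37 of 38 were higher (median 0.78, camera p = 2.39e-49; p = 4.09e-05 with an estimated correlation). Across 14366 genes, which are not independent replicates, the log2 fold changes of the comparisons had a Spearman correlation of −0.35. This absolute value was reached by 2 of the 35 splits of the Ctrl and Mut libraries, the real one included. With the set of hormone-responsive genes held fixed, the 14 opposite calls became 4 without Ctrl replicate 2, 3 without Ctrl replicate 3, 3 without Ctrl replicate 4, 1 without Mut replicate 1, 3 without Mut replicate 4 and 8 with sex as a covariate. With sex as a covariate the medians were −1.02 for the raised and 0.54 for the lowered genes. The median of the raised genes stayed between −1.12 and −0.95 when any Ctrl or Mut library was omitted.

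**Figure D3:**
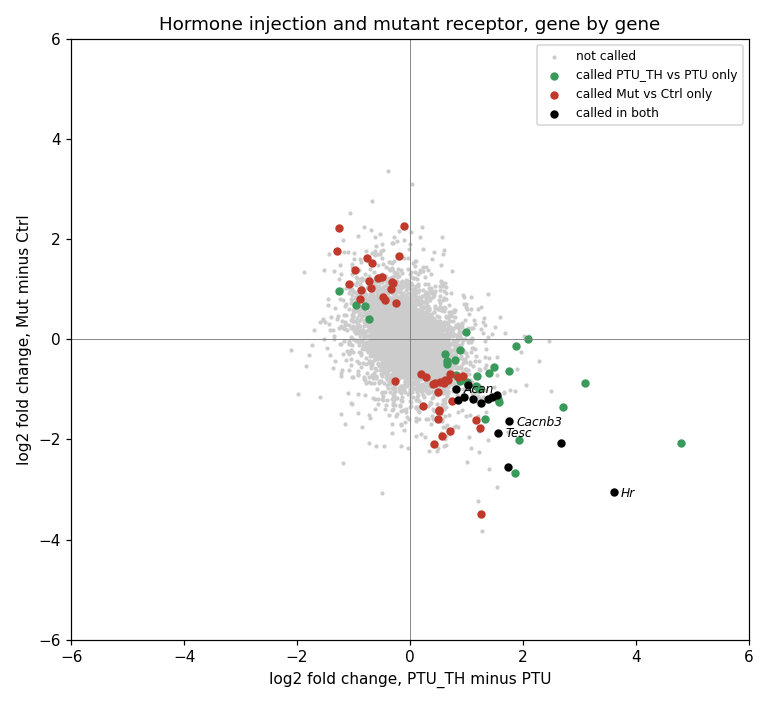
Log2 fold change of 14366 genes for PTU_TH minus PTU (horizontal axis) and Mut minus Ctrl (vertical axis); grey points are genes called in neither comparison and coloured points those called in 1 or both. The 14 genes called in both lie in the lower right part, raised by the hormone and lower in Mut.

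PTU mice were compared with untreated Ctrl mice to ask what lowering the hormone does. The libraries of these groups form separate sets with different gene lists, so the diet and the library set cannot be told apart. Hr fell from 14.6 CPM in Ctrl to 3.93 CPM in PTU (log2 fold change −1.90 ± 0.28 SE, edgeR adjusted p = 0.000590). Cacnb3 (−1.13), Sema7a (−0.66) and Abcd2 (−0.49; adjusted p = 0.0845 without PTU replicate 6) fell as well. Rxrg, a retinoid X receptor gene, rose by 1.80 on the log2 scale (edgeR adjusted p = 0.126 without PTU replicate 6). Of 18 hormone-induced genes, 15 were negative with 3 called, also 3 when adjusted over the list alone. The list did not pass camera (adjusted p = 0.478). Chaperone genes of the heat shock list fell in part, with Hspa8 at −1.58, Hsp90aa1 at −0.96 and Hspa1b at −2.23 called of 21. When adjusted over the list alone, 5 were lower and 2 higher (camera adjusted p = 0.671). Sv2c, a synaptic vesicle protein gene, fell by 2.58 and Kcnk1, a background potassium channel gene, by 1.41 on the log2 scale. Lower in PTU_TH against Ctrl too were Sv2c (−2.53), Kcnk1 (−0.97), Hspa8 (−1.33) and Hsp90aa1 (−0.96), while Hspa1b was not called there. The falls of the former were thus also present after the injection.

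Far more genes differed here than within either set: 2804 of 16496 by edgeR, 722 higher and 2082 lower in PTU, and 4283 without PTU replicate 5. At an unadjusted p under 0.05 there were 4758, and 27.6% of all genes had no overlap between the groups, against 5.71% by chance. Of the 2804, 666 had a count of 0 in every library of 1 group, 644 of them in PTU. Pde2a (at least 872-fold lower at a floor of 3 counts per library; 64.3% of its exonic bases shared), Matr3 (at least 790-fold) and Eno1b (at least 679-fold) had no count in PTU. Rgmb (at least 436-fold higher), Wdr74 (at least 434-fold) and Atp6v0c (at least 377-fold) were at 0 in Ctrl. Of the 2804 genes, 2009 were called the same way between PTU_TH and Ctrl. Of these, 2007, or 71.6% of the 2804, were not called between PTU_TH and PTU. The last condition removed few because only 43 genes were called there. Both comparisons use the same Ctrl libraries, and the share expected from this alone was not derived. With limma-voom 5653 genes were called, 2292 higher and 3361 lower. Without PTU replicate 6, 254 were higher and 1809 lower, and without PTU replicate 7, 306 and 1898. The marker covariate gave 264 higher and 1794 lower.

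PTU_TH mice were compared with Ctrl to ask where the injection left the levels, with the same confounding of treatment and library set. Hr rose above Ctrl, from 14.6 to 46.8 CPM (log2 fold change 1.69 ± 0.13 SE, edgeR adjusted p = 1.39e-06). Dbp (1.48), Flywch2 (1.25), Klf9, a hormone-induced transcription factor (0.60), Sema7a (0.58), Kcng4 (1.04) and Scn4b (0.63) rose too. Acan (0.41; adjusted p = 0.0892 without Ctrl replicate 4), Ncan (0.48; adjusted p = 0.0578 without Ctrl replicate 3) and the hyaluronan synthase gene Has3 (0.69) rose. Of 23 perineuronal net genes, 4 were higher and 1 lower, both over all genes and adjusted over the list alone (camera adjusted p = 0.0653). The peptide genes Cort (−1.81), Pthlh (−1.26), Crhbp (−0.91) and Tac1 (−0.73; adjusted p = 0.0678 without PTU_TH replicate 1) fell. These were 4 of 15 peptide genes over all genes, and 5 fell when adjusted over the list alone (camera adjusted p = 0.553). The hormone-induced list passed camera upward with 6 of 18 called, also 6 adjusted over the list alone (adjusted p = 0.0449; adjusted p = 0.742 with an estimated correlation; 0.0943 without Ctrl replicate 4). No other list passed camera. By fry the perineuronal net (adjusted p = 0.0198), hormone signalling (adjusted p = 0.0198) and GABA synthesis and receptor lists (adjusted p = 0.0388) passed as well. In all, 2814 of 15814 genes differed, 746 higher and 2068 lower, with 4743 at an unadjusted p under 0.05. Without overlap were 23.2% of genes, against 2.86% by chance, and 512 of the 2814 were at 0 in every library of 1 group. A surrogate variable raised the count to 4508.

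Whether PTU and the mutant receptor moved the same genes relative to Ctrl was examined with the shared controls taken into account. Hr, Cacnb3 and Sema7a fell in both comparisons. Over 17207 genes the log2 fold changes had a Pearson correlation of 0.08 and a Spearman correlation of 0.17, below the 0.45 and 0.42 that simulated unchanged groups gave against the same controls over 100 simulations. The covariance was 0.0494 against a simulated 0.0693, a difference of −0.0199. With the controls split 2 and 2 in 6 ways the Pearson correlation was −0.01 on average (−0.04 to 0.00). Genes called lower in both were 13, against 4.64 expected of independent lists, and genes called higher in both were 9, against 0.791. These expectations leave out the shared controls. The simulated groups held no difference between the library sets, whereas PTU and Ctrl belong to different sets. Neither the simulations nor the split controls can therefore decide whether PTU and the mutant receptor share effects.

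Pvalb, which encodes parvalbumin and drives the Cre line, and the hormone receptor genes were followed in each comparison. Pvalb measured 120 ± 9.21 CPM in Ctrl and 77.4 ± 12.9 in Mut (log2 fold change −0.63, edgeR adjusted p = 0.0780). It measured 97.8 ± 9.30 CPM in PTU and 135 ± 13.9 in PTU_TH (0.47, edgeR adjusted p = 0.277). It passed in neither. It did pass without Mut replicate 2 (−0.71, edgeR adjusted p = 0.0349). Thra did not pass between PTU_TH and PTU (−0.27, edgeR adjusted p = 0.746). Thrb, the gene of receptor beta, varied widely between libraries, with 387 ± 195 CPM in PTU_TH and 341 ± 224 in PTU (0.19, edgeR adjusted p = 1.00). It measured 470 ± 119 CPM in Mut against 445 ± 159 in Ctrl (0.08, edgeR adjusted p = 0.981). Between PTU and Ctrl, Pvalb (−0.30), Thra (0.38) and Thrb (−0.41) did not pass. Without PTU replicate 5, Thra (0.45, edgeR adjusted p = 0.0364) and Thrb (−1.07, edgeR adjusted p = 0.0203) did. The 27 parvalbumin neuron genes did not pass camera as a list in PTU_TH against PTU (adjusted p = 0.247) or in Mut against Ctrl (adjusted p = 0.945 with an estimated correlation). Acan was called of 27 in the former, also 1 when adjusted over the list alone. Acan and Tac1 were called in the latter, where 2 were higher and 3 lower when adjusted over the list alone, Pvalb among the lower.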

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

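In this part, the tests with sex in the model, of the median of the hormone-raised genes, of uneven sex and long-gene coverage, of overlapping gene models and of near-identical copies were chosen after the results were seen. Of 82 groups of 4 libraries, 3 held a library apart from the other 3 by Dixon's gap ratio, and chance alone gives about 1 in 20. PTU_TH replicate 2 had 19141683 counts against 12957838 to 13965520 in the others (ratio 0.837). Zcchc12, a gene raised in Mut, measured 23.8 CPM in Mut replicate 1 against 18.6 to 19.0 in the others (ratio 0.929). Sema7a measured 13.3 CPM in Mut replicate 3 against 24.9 to 25.8 in the others (ratio 0.931). For Sema7a, all 4 Mut values lie below those of the Ctrl libraries.

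The number of genes that responded to the hormone may partly reflect how the libraries vary. Of the 35 splits of the PTU and PTU_TH libraries, 3, the real one included, called at least 43 genes, so chance cannot be excluded by this count; the highest other split, with 3663, sets the libraries with Y-linked counts against those without. With sex in the model, the fold changes of the 43 kept a median ratio of 0.992 (quartiles 0.969 to 1.01) to the original ones. The groups do not overlap for any of the 43. Y-linked counts were present in 2 of 3 PTU and 2 of 4 PTU_TH libraries. A ratio near 1 was therefore likely from the outset, and it cannot decide whether that structure contributes. With sex in the model the real split called 335 genes, and 1 of 34 splits, the real one, reached that number, with 2 in the highest other. A response of parvalbumin neurons to the hormone stays as a hypothesis, and whether sex or long-gene coverage sets the structure was not separated, since they go together in these 7 libraries.

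The opposite movement of hormone-responsive genes in Mut could come from chance, from the unequal sexes of Mut and Ctrl, or from the receptor. Only the real split of the 8 libraries, 1 of 35, called as many as 59 genes (7 in the highest other). Only it, 1 of 35, put the median of the 39 raised genes as far from 0 (−0.99, against −0.55). Chance is unlikely for both, although 1 of 35 is the smallest share these splits can give. The test of the median was chosen after the results were seen. For the correlation across all genes, 2 of 35 splits lay as far from 0 (−0.35 and 0.35), and the other sets the Y-linked libraries against the rest, so chance is not excluded there (absolute values were compared, although the test was first written for values below 0). With sex in the model the fold changes of the 59 genes kept a median ratio of 1.03 (quartiles 0.986 to 1.08). The groups of these genes do not overlap, although each group holds libraries with and without Y-linked counts. Genes set by sex alone were thus unlikely among the 59, and a ratio near 1 was likely from the outset. The ratio cannot tell how far sex contributes. A loss of hormone response through the dominant negative receptor is consistent with these tests and remains a hypothesis, tested in other libraries than those that gave the gene sets.

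The many genes that separate PTU or PTU_TH from Ctrl may come from the library sets, from the diet or from both. Chance is unlikely, since 1 of 35 splits reached 2804 genes for PTU (2 in the highest other) and 1 of 35 reached 2814 for PTU_TH (1 in the highest other). A share of 1 in 35 is the smallest these splits can give. Of the genes called in PTU, 71.6% were called the same way in PTU_TH and not called between PTU_TH and PTU. The shared Ctrl libraries favour such agreement. The set and the diet cannot be told apart by it, because both treated groups received PTU and both are in the same set. For the 666 genes at 0 in 1 group, overlapping gene models argue little, since a shared exon was 0.700 times as frequent among them as among all genes tested (23.6% against 33.7%). Pseudogenes were 5.31 times as frequent among them (45.4% against 8.54%), so reads from near-identical copies counted differently in the sets are a candidate explanation for these genes, one that was written after their gene types had been looked at and that these data cannot decide.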

How the results depend on the processing

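Sex as a covariate and the exclusion of genes with shared exons were chosen after seeing the data; the other settings were fixed before. No called gene among those named changed sign under any setting in which it was tested, and where a call or count moved the cause was not tested. The hormone response in PTU mice went from 43 genes to 203 with DESeq2 (158 higher, 45 lower), 171 with voom, 1059 with a surrogate variable, 155 with the marker covariate and 335 with sex as a covariate. It ranged from 5 to 29 with 1 library omitted. The 59 genes of Mut against Ctrl became 399 with DESeq2, 331 with voom, 196 in a fit to all 4 groups, 177 with a surrogate variable, 90 at a floor of 1 CPM, 39 with the 2-fold threshold and 31 with sex as a covariate. They ranged from 11 to 103 with 1 library omitted. PTU against Ctrl moved to 5653 with voom and ranged from 2061 to 4283 with 1 library omitted (4283 without PTU replicate 5), and was 2034 without shared exons. PTU_TH against Ctrl moved to 4508 with a surrogate variable and 1832 with the 2-fold threshold, ranged from 2380 to 3270 with 1 library omitted, and was 2006 without shared exons. Upper quartile and RLE scaling left each of these 4 counts within 1.5 times. Lists past the test for PTU_TH against PTU fell from 11 to 0 with an estimated correlation, 2 with fry and 7 with sex as a covariate (4 to 12 with 1 library omitted). For Mut they fell from 3 to 0 and to 1 with fry (2 to 3). For PTU_TH against Ctrl they went from 1 to 0, 4 with fry and 3 with sex as a covariate (0 to 3). For PTU against Ctrl they stayed at 0 with 1 library omitted. With sex as a covariate in the Mut against Ctrl fit, genes called in opposite directions fell from 14 to 8 and the correlation from −0.35 to −0.22. With 1 Ctrl or Mut library omitted they ranged from 1 to 17 and from −0.38 to −0.25. The PTU_TH against PTU fit was held fixed for these values and for the medians that follow. No PTU or PTU_TH library was omitted for them. The medians of the raised genes (−0.99) and the lowered genes (0.67) kept their sign and call. They were −1.02 and 0.54 with sex as a covariate, −1.15 and 0.67 with the replicate block, −1.19 and 0.96 for genes changed at least 2-fold, and −1.12 to −0.95 and 0.60 to 0.75 with 1 library omitted. With split controls the PTU and Mut Pearson correlation went from 0.08 to a mean of −0.012, the splits lying on both sides of 0 (−0.04 to 0.00), and the covariance from 0.0494 to −0.00865. Pvalb passed in PTU_TH against PTU with a surrogate variable (0.45) and with sex as a covariate (0.43), and in Mut with DESeq2 (−0.63), all 4 groups (−0.63), voom (−0.71) and a surrogate variable (−0.69). With 1 library omitted it ranged from 0.39 to 0.53 and from −0.71 to −0.55. Thra in Mut lost its call with the replicate block (−0.84) and with sex as a covariate (−0.83) and ranged from −0.93 to −0.78. In PTU against Ctrl, voom called Thra (0.44), Pvalb (−0.31) and Thrb (−0.84), and a surrogate variable called Pvalb (−0.31). With 1 library omitted these ranged from 0.30 to 0.45, −0.34 to −0.24 and −1.07 to −0.12. Thrb had no stable sign in the other comparisons, in none of which it was called. In PTU_TH against PTU it was 0.19, −0.34 with the marker covariate and −0.19 to 0.87 with 1 library omitted. In Mut it was 0.08 (−0.08 to 0.35) and in PTU_TH against Ctrl −0.24 (−0.59 to 0.04). Same-numbered Ctrl and Mut libraries deviated together with correlations of 0.12, 0.20, −0.02 and 0.08. The highest correlations of these Ctrl libraries with the other Mut libraries were 0.03, −0.008, 0.13 and 0.002. The same-numbered library was thus the closest for Ctrl replicates 1, 2 and 4, and a pairing is not excluded. The labels do not state that the numbers mark pairs, so the main fit used no block. As a replicate block the numbers gave 82 genes for Mut, with 52 of the 59 among them, 14 opposite calls, and 2424 genes for PTU_TH against Ctrl. Over the settings other than omissions, called named genes kept their call in 1785 of 1864 cases, and uncalled ones gained it in 96 of 900. With 1 library omitted the call was kept in 1021 of 1277 cases and gained in 8 of 643. Depth limits low genes: with 12957838 counts in the smallest library, 3 counts are the floor used.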

Other observations

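The tests named in this part belong to the planned list comparisons, and none was chosen after the result was seen. Several gene groups of parvalbumin neurons showed little or scattered movement. Of 18 genes of thyroid hormone signalling, none was called in PTU_TH against PTU, where 2 higher and 1 lower passed when adjusted over the list alone, the coactivator gene Ncoa3 (0.53) among them (limma camera adjusted p = 0.791). In Mut, Thra was called of 17, with 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.438). Circadian genes had Dbp called of 17 after the hormone, with Hlf and Nr1d2 added when adjusted over the list alone (camera adjusted p = 0.0966). In Mut none of 18 was called, and 2 were higher and 4 lower adjusted over the list alone, among them Bhlhe40 (−0.80) and Nr1d2 (−0.41; camera adjusted p = 0.285). Hormone-repressed genes did not pass in Mut (camera adjusted p = 0.889), with Dgkg (0.96) higher and Hapln1, a link protein of perineuronal nets (−0.57), lower when adjusted over the list alone.

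After the hormone, mitochondrial and respiratory chain genes passed camera with a median of 0.06 (33 of 42 positive, adjusted p = 0.0463; adjusted p = 0.756 with an estimated correlation; 0.874 without PTU replicate 5). Heat shock and stress genes passed with a median of 0.10 (17 of 20 positive, adjusted p = 0.0457; adjusted p = 0.679 with an estimated correlation; 0.663 without PTU replicate 5). No member of either was called over all genes or adjusted over the list alone. Lists that did not pass camera there were GABA synthesis and receptors (adjusted p = 0.927), glutamate receptors (0.376), vesicle release (0.376), cholesterol synthesis (0.376), other interneurons (0.220), oligodendrocytes (0.376), microglia (0.941) and endothelial and mural cells (0.436). In Mut the camera adjusted p was 0.671 for GABA synthesis and receptors, 0.731 for glutamate receptors, 0.568 for vesicle release, 0.438 for cholesterol synthesis, 0.568 for heat shock and 0.227 for other interneurons. It was 0.438 for excitatory neurons, 0.438 for astrocytes, 0.568 for oligodendrocytes, 0.227 for microglia and 0.976 for endothelial and mural cells. Mitochondrial genes had an adjusted p of 0.958 with an estimated correlation. Medians and the direction of the test differed in sign for microglia after the hormone (median 0.02, test downward). In Mut they did so for endothelial and mural cells (median 0.57, test downward), GABA synthesis and receptors (−0.05, upward), perineuronal net genes (0.01, downward) and hormone signalling genes (0.01, downward). Precursors of oligodendrocytes, erythrocytes and sex-linked genes had fewer than 5 members measured in these comparisons. Bmp4, of the precursor list, was at 4.05 ± 1.06 CPM in PTU_TH and 1.74 ± 0.845 in PTU. It was at 0.188 ± 0.156 CPM in Mut and 1.79 ± 0.755 in Ctrl, and it passed in neither over all genes (edgeR adjusted p = 0.404 and 0.0810).

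Klf9 and Hr are both known targets of the hormone, but only Hr was called in Mut (log2 fold change −3.06), a call kept in 2 of 8 omissions. Klf9 measured 25 ± 8.88 CPM in Mut and 37.6 ± 2.04 in Ctrl (log2 fold change −0.59, edgeR adjusted p = 0.395), with overlapping ranges. Hr was lower in 4 of 4 Mut libraries than in any Ctrl library (0.467 to 3.83 against 12.4 to 16.0 CPM). Whether these genes differ in their response was not tested.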
